A study of Arabidopsis thaliana with 12 samples.

How the data were processed

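Transcript levels were measured on 12 Affymetrix ATH1 arrays of Arabidopsis aerial parts. The arrays form 6 groups of 2: wild type (wt), the abscisic acid (ABA) deficient mutant aba3-1, and the lines S14-150, S15-118, S58-2 and S82-2. The series title speaks of suppressor mutants of aba3-1, and the 4 lines are taken here to be these suppressors, since no label says so of each line. Per the labels' protocols the plants grew at 21 °C with 8 h light and 16 h dark, and 20 µg of amplified RNA was labelled for each array. Extracted RNA ranged from 5.1 to 15 µg per sample, per the labels.

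The deposited values are log2 signals of probe sets, made with GCRMA per the submitters' processing notes, in a version not given in the sources used here. The log base is not stated in the table. It was taken as 2, the scale of GCRMA itself, and the range and quartiles of the values did not contradict this. The table holds 22810 probe sets, of which 64 controls were left out of the tests, leaving 22746. A probe set was tested when its log2 value was above 4 in at least 2 of the 12 arrays, which left 11561.

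Gene names came only from the tables at hand. They pair 13513 probe sets with 1 gene, 503 with several and 8730 with none, so that 6073 of the tested probe sets (52.5%) have 1 gene and 921 of these a symbol other than the locus. A gene without a symbol is given by its locus. ABA3, the gene mutated in aba3-1, has no probe set paired with it in these tables and is not analysed here.

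Group means were fitted over all 12 arrays in 1 linear model with limma 3.58.1 (lmFit, contrasts.fit and eBayes) in R 4.3.3, with 6 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over the probe sets tested, and a probe set was called at an adjusted p under 0.05. All adjusted p-values below are from limma unless another source is named. The comparisons were aba3-1 with wt, each line with aba3-1 and with wt, the mean of the 4 lines with aba3-1, each line with the mean of the other 5 groups, all pairs of lines, and an F test over the 6 groups. For the contrast of a line with the other 5 groups, both of its arrays also had to lie outside the range of the other 10 arrays. No sample label says that the 2 replicates of a group are separate plants or batches, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision.

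The replicate numbers of the labels pair the arrays across groups. In all 15 pairs of groups the deviations of the arrays from their group means correlated between equal numbers, with r across probe sets from 0.708 to 0.872, and all 12 arrays correlated best with an array of their own number. This was decided from the correlations and before calls were compared. The fit fixed before the data were examined has no block. The fit with the replicate number as an additive term is given beside it as the blocked fit. The pairs of groups that include S58-2 had the lowest correlations of deviations, at most 0.724, and without S58-2 the lowest was 0.798. The additive term may thus describe the S58-2 arrays less well than the others, which limits the blocked counts of S58-2.

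Genes named for a comparison were chosen by a rule fixed before the data were examined. Up to 6 higher and 6 lower probe sets were taken per comparison with wt or aba3-1 and per contrast of 1 line with the other groups, by the largest absolute log2 fold change. They had to be called, to change by at least 1 log2, to have no overlap between the arrays of the groups, and to map to exactly 1 gene. From each gene list, up to 2 called members with the largest fold per direction were chosen, or, where none was called, up to 2 with the highest mean. Not all of these list members are reported below. Genes named from the blocked fit, and any others outside this rule, were chosen after their values were seen.

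The gene lists were also fixed before the data were examined, 29 lists with 448 loci. Since few genes have a paired probe set, only 3 lists reached the minimum of 3 tested members: the cold regulon, expansins with xyloglucan endotransglucosylases, and photosynthesis. They were tested in 10 comparisons with camera of limma, two-sided, with a preset correlation between genes of 0.01, and again with an estimated correlation. No list of ABA metabolism, ABA receptors, clade A phosphatases or molybdenum cofactor genes had a tested member, so these lists were not analysed here.

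Recovery towards wt was measured on probe sets chosen by an aba3-1 to wt difference of at least 1 log2 in the arrays of 1 replicate number and measured in those of the other number. It is the median change of the line from aba3-1, signed by the direction towards wt, divided by the median distance of wt from aba3-1, averaged over both choices. Its bootstrap interval covers probe sets, not plants. Shared calls between lines were set beside 50 simulations of unchanged lines against the same aba3-1 arrays. A further 50 simulations, with S14-150 set equal to aba3-1 and S82-2 to wt and the measured means taken as true, gave the no-change values for probe sets moved or called back and for calls of S82-2 against wt.

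The scripts were tested on simulated data for the aba3-1 to wt comparison over 11561 probe sets. Without the block, limma recovered 5% of the changes of 1 log2 and 59% of those of 2 log2. With the block it recovered 79% and 100%, and 3.76% of the blocked calls were false. The simulated data held an additive replicate term equal in all groups and independent noise, just as the blocked fit assumes. The share of false calls in the real data was thus not measured. The simulated recovery shares came back within 0.00397.

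The alternatives tried were no filter, a mean above 6, quantile normalization, median centring, trend and robust variance, array weights, only the groups compared, the replicate block, Bonferroni adjustment, a fold threshold, each array left out, and other choices for the lists and for recovery. Fits without the S58-2 arrays, the blocked fits with 1 array left out, and the no-change values were added after the data were seen. Figures were drawn with matplotlib 3.10.9.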

Results

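The data set holds 12 arrays, with 2 arrays in each of 6 groups. It compares wild type plants, the ABA-deficient mutant aba3-1, and 4 suppressor lines, S14-150, S15-118, S58-2 and S82-2. ABA is the hormone that closes stomata in drought, and aba3-1 carries a mutation in the gene of molybdenum cofactor sulfurase. The comparisons ask how aba3-1 differs from wild type and how far the transcript profile of each line has moved from that of its parent. The median signal was between 3.58 and 3.73 on the log2 scale on the 12 arrays, and 45.5% to 46.9% of probe sets lay above the floor of 4. The first principal component held 52.6% of the variance and parted the arrays by replicate number. The second component held 26.5%, with wt and S82-2 at one end and S58-2 and S15-118 at the other.

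**Figure D1:**
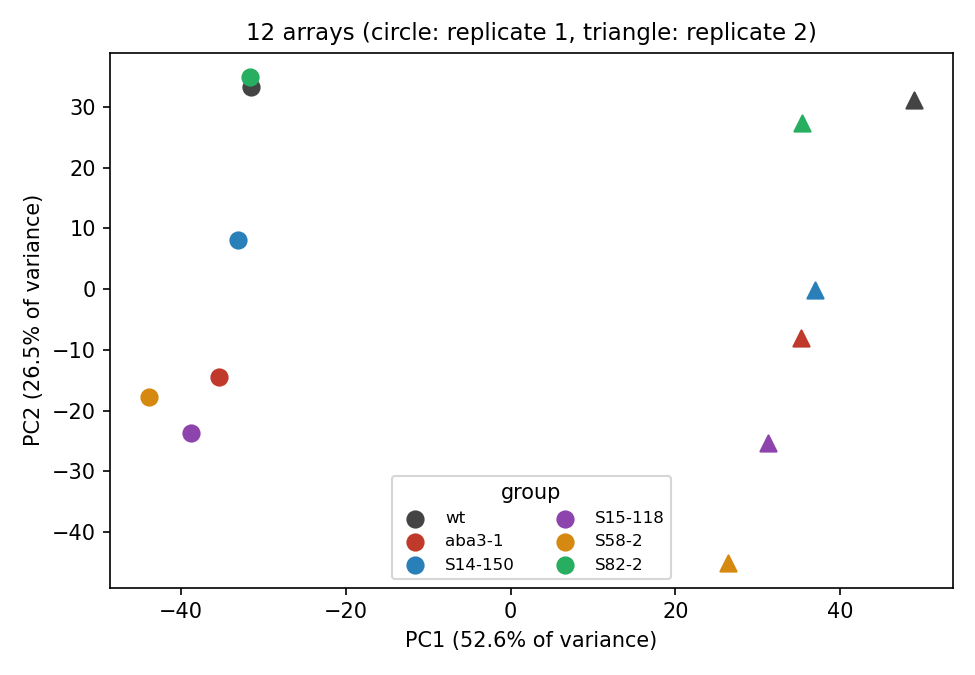
First 2 principal components of the 12 arrays over the tested probe sets (PC1 52.6% and PC2 26.5% of the variance, unitless scores), colored by group, with circles for replicate 1 and triangles for replicate 2. Replicate numbers separate along PC1, and wt and S82-2 lie together along PC2.

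Among the tested probe sets, more were called higher in aba3-1 than in wt than lower. AT1G57630, which encodes a protein with a TIR domain as found in immune receptors, was 2.95 log2 higher (SE 0.41, n = 2 per group, adjusted p = 0.0360). AT5G18470, a lectin-like protein, was 2.84 higher (SE 0.36, adjusted p = 0.0318), and AT4G12490, a protein of the lipid-transfer type, was 2.74 higher (SE 0.32, adjusted p = 0.0280). QQS, an orphan gene linked to starch content, rose from 5.04 ± 0.77 (SD, n = 2) in wt to 7.94 ± 0.11 in aba3-1, a change of 2.89 (SE 0.32, adjusted p = 0.0198). Among lower genes, ZW9 changed by -2.30 (SE 0.34, adjusted p = 0.0361), the remorin gene AT5G23750 by -1.92 (SE 0.28, adjusted p = 0.0360) and the MATE transporter gene AT5G44050 by -1.68 (SE 0.22, adjusted p = 0.0318). The other named genes were AT2G18690 and AT4G00700 on the higher side, and AT2G30695, AT4G38690 and AT5G13240 on the lower side, with changes from -1.95 to 2.94. Of the 56 changes chosen by the naming rule against wt or aba3-1, 31 have a group mean under the floor of 4. They are differences between fitted signals, one of them near background.

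In all, 52 of 11561 probe sets were called between aba3-1 and wt with limma, 43 higher and 9 lower in aba3-1. The blocked fit called 576, 378 higher and 198 lower, and these include all 52. Without the filter limma called 6, 2 higher and 4 lower, so that the direction turned. Leaving out any 1 of the 4 arrays of these groups lowered the count without the block, to between 1 (without aba3-1 replicate 1) and 3 (without wt replicate 1). With the block these counts lay between 80 (without aba3-1 replicate 1) and 328 (without aba3-1 replicate 2).

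The blocked fit called further genes in aba3-1, and 4 of them are given with both values. AT2G43570, given the symbol CHI and described as a putative chitinase, was 4.13 higher in aba3-1 (SE 0.71, adjusted p = 0.0642, blocked adjusted p = 0.000226). The defensin gene PDF1.2, a marker of jasmonate and ethylene responses, was 2.78 higher (adjusted p = 0.0599, blocked adjusted p = 0.00509). WRKY53, a transcription factor of leaf senescence, was 2.02 higher (adjusted p = 0.0575, blocked adjusted p = 0.00378). The cold-induced gene COR15A was at 8.18 ± 1.42 (SD, n = 2) in aba3-1 and 10.22 ± 1.34 in wt, a difference of -2.05 (adjusted p = 0.835, blocked adjusted p = 0.000368). CHI was named after its values were seen.

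**Figure D2:**
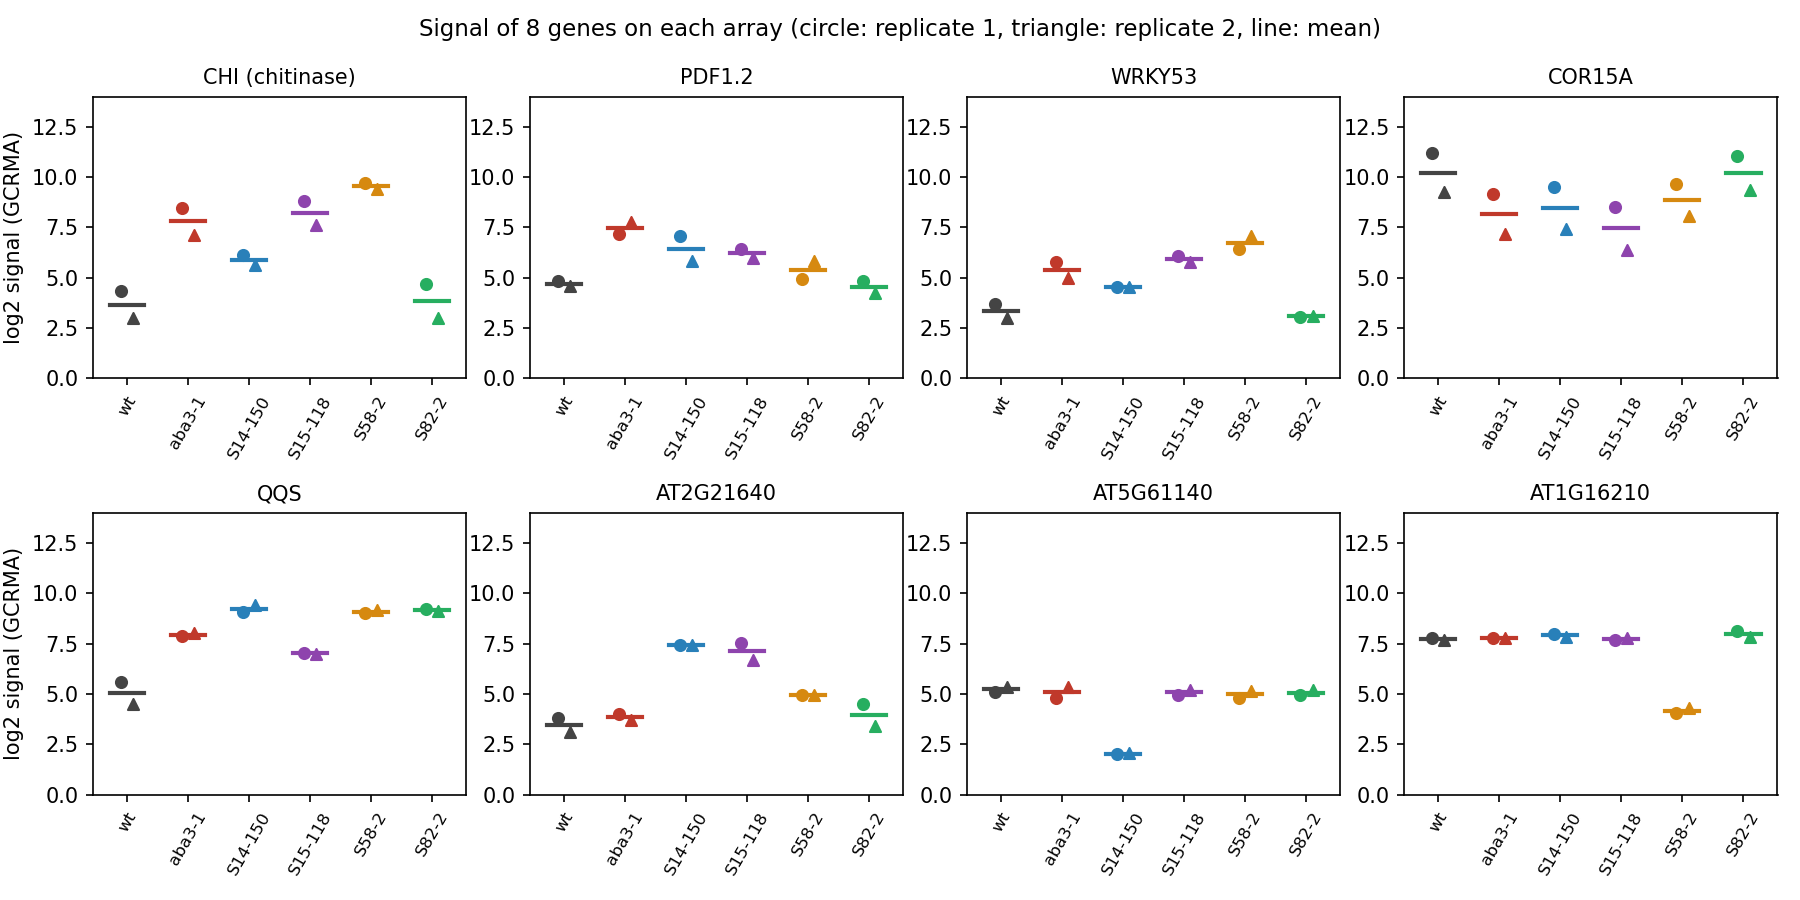
Signal (log2, GCRMA) of 8 genes on each of the 12 arrays, with circles for replicate 1, triangles for replicate 2 and a line at the mean of each group. WRKY53 is near 3 in wt and S82-2 and highest in S58-2 (6.74), AT5G61140 is low in S14-150 alone (2.04) and AT1G16210 in S58-2 alone (4.18).

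Several genes that were higher in aba3-1 than in wt were lower in S82-2 than in aba3-1. AT2G18690 changed by -3.21 against aba3-1 (SE 0.38, n = 2 per group, adjusted p = 0.0151), AT5G18470 by -3.19 (SE 0.36, adjusted p = 0.0151), AT1G57630 by -2.82 (SE 0.41, adjusted p = 0.0327) and AT4G00700 by -2.79 (SE 0.35, adjusted p = 0.0181). PDF1.2 fell from 7.48 ± 0.44 (SD, n = 2) in aba3-1 to 4.53 ± 0.42 in S82-2 (log2 change -2.96, adjusted p = 0.0459), and its level in wt was 4.70 ± 0.17. WRKY53 changed by -2.30 (adjusted p = 0.0307), and AT5G52760, of a heavy-metal-associated domain family, by -2.98 (adjusted p = 0.0487). AT2G30695 was 2.14 higher (SE 0.30, adjusted p = 0.0293). COR15A was 2.04 higher, with an adjusted p of 0.853 and a blocked adjusted p of 0.000225.

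Between S82-2 and aba3-1, limma called 58 probe sets, 5 higher and 53 lower in S82-2, and the blocked fit called 677, 181 higher and 496 lower. Each of the 4 arrays, when left out, lowered the count without the block, to between 0 (without S82-2 replicate 1) and 30 (without aba3-1 replicate 2). With the block, these counts lay between 125 (without aba3-1 replicate 1) and 420 (without aba3-1 replicate 2). Against wt, only QQS was called in S82-2, 4.12 higher (SE 0.32, adjusted p = 0.0102). The blocked fit called 54 probe sets between S82-2 and wt, 29 of them also called the same way between aba3-1 and wt, but with 1 array left out the 54 became 1 (without S82-2 replicate 2) to 6 (without wt replicate 1). Both comparisons use the same wt arrays. Independent lists, which leave out the shared wt arrays, would share 0.523 higher and 0.651 lower, against 8 and 21 observed. A simulated line equal to wt had 0.12 blocked calls on average, 0.06 of them called the same way in aba3-1. These are too few to be set against the 29 of 54. Across numbers, where no array is shared, the covariance of the 2 differences from wt was 0.0145.

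Few genes were called between S14-150 and aba3-1. AT5G61140, which encodes a helicase of the spliceosome, was at 2.04 ± 0.03 (SD, n = 2) in S14-150 and 5.08 ± 0.36 in aba3-1, a change of -3.04 (SE 0.23, adjusted p = 0.00945). Its level in S14-150 is under the floor of 4. AT5G09570, of a mitochondrial family with paired cysteine motifs, was 2.73 higher (SE 0.27, adjusted p = 0.0374), measured from an aba3-1 level of 2.69, also under the floor. AT2G21640, an oxidative stress gene, was 3.59 higher (SE 0.42, adjusted p = 0.0891, blocked adjusted p = 0.000503). AT5G61140 and AT5G09570 were the 2 calls without the block, 1 lower and 1 higher, and the blocked fit called 10, 4 higher and 6 lower, and 64 without the S58-2 arrays, 6 higher and 58 lower. Each array of these groups changed the count when left out, to 0 without S14-150 replicate 1 and to at most 1 (without aba3-1 replicate 1).

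In S15-118, 4 genes were called higher. AT1G33840 was 3.48 higher than in aba3-1 (SE 0.24, n = 2 per group, adjusted p = 0.00417), AT2G04460 was 3.17 higher (SE 0.31, adjusted p = 0.0308), and AT5G09570 was 2.57 higher (SE 0.27, adjusted p = 0.0351). KELP, a transcriptional coactivator, was 1.61 higher (SE 0.17, adjusted p = 0.0351). AT2G21640 was 3.28 higher (adjusted p = 0.105, blocked adjusted p = 0.00120). No gene was called lower without the block; the blocked fit called 10, 7 higher and 3 lower. The count of 4 went to 0 without aba3-1 replicate 1 and stayed at 4 without S15-118 replicate 2.

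In S58-2, AT1G16210 alone was called against aba3-1. It was at 4.18 ± 0.19 (SD, n = 2) in S58-2 and 7.79 ± 0.01 in aba3-1, a change of -3.62 (SE 0.18, adjusted p = 0.000276). The blocked fit called 12, 10 higher and 2 lower, among them the linker histone gene HIS1-3, 1.35 higher (adjusted p = 0.249, blocked adjusted p = 0.0213), and AT4G12490, 2.31 higher (adjusted p = 0.249, blocked adjusted p = 0.0213). The differences between S58-2 and aba3-1 correlated weakly between the replicate numbers (r = 0.114 across genes, which are not independent replicates). S58-2 replicate 1 had a ribosomal RNA control signal of 3.77, against 7.19 to 9.78 on the other arrays, and replicate 2 had the least extracted RNA (5.1 µg). Without S58-2 replicate 1 the count was 2, and with the block it was 548.

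Relative to wt, S58-2 and S15-118 had many more calls than S14-150 and S82-2. S58-2 had 373 calls, 252 higher and 121 lower (1216 and 1405 in the blocked fit, where the direction with more calls turned), and S15-118 had 160, 128 higher and 32 lower (861 and 796 in the blocked fit). S14-150 had 7, 4 higher and 3 lower (83 and 78 in the blocked fit, but 4 and 6 without the filter), and S82-2 had 1 higher (16 higher and 38 lower in the blocked fit). In S58-2, CHI was 5.87 higher than in wt (SE 0.71, adjusted p = 0.00632) and AT4G12490 5.05 higher (SE 0.32, adjusted p = 0.000819). In S15-118, these 2 genes were both 4.54 higher (adjusted p = 0.0254 and 0.00189). QQS was higher than in wt in S14-150 (4.20, adjusted p = 0.00444) and S58-2 (4.04, adjusted p = 0.00182). UGT76C2, a cytokinin glucosyltransferase gene, was lower in S58-2 (-1.90, SE 0.24, adjusted p = 0.00698), and AT5G13240 was lower in S14-150 (-1.43, adjusted p = 0.0244). Without wt replicate 2 the counts were 71 for S58-2 and 8 for S15-118; without S58-2 replicate 1 the first was 402. The count of S14-150 was 0 without S14-150 replicate 1, and that of S82-2 was 0 without S82-2 replicate 1 and 2 without wt replicate 1.

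**Figure D3:**
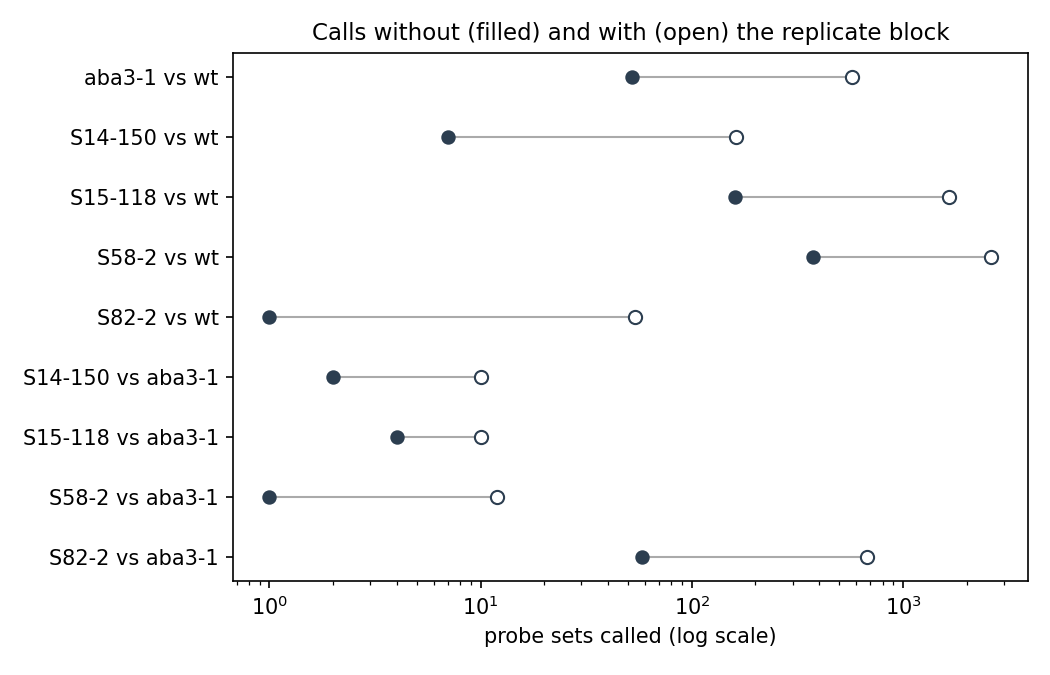
Number of probe sets called at an adjusted p under 0.05 (limma) in 9 comparisons, on a log axis, without the replicate block (filled) and with it (open). S58-2 against wt has the most calls in both fits (373 and 2621).

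S82-2 and S14-150 lay between aba3-1 and wt, and S15-118 and S58-2 did not. S82-2 had moved 0.941 of the distance to wt (SD 0.0199 of the 2 choices; bootstrap interval 0.879 to 0.989), and S14-150 0.377 (SD 0.0772; 0.342 to 0.418). S15-118 lay slightly farther from wt than aba3-1, at -0.190 (SD 0.109; -0.224 to -0.169). S58-2 was at -0.458 (SD 0.579, bootstrap interval -0.504 to -0.414). It was at -0.867 for probe sets chosen in number 1 and measured in number 2. For those chosen in number 2 and measured in number 1 it was at -0.0484, close to aba3-1. A position of S58-2 beyond aba3-1 thus rests on its replicate 2 array, and the bootstrap interval holds neither of the 2 values. Of the 52 probe sets called between aba3-1 and wt, 50 had moved back towards wt in S82-2 and 49 in S14-150, against 13 in S15-118 and 8 in S58-2. These counts use the same aba3-1 arrays for both differences, and a simulated line equal to aba3-1 moved back in 60.4% of the 52 probe sets of lowest p. The simulations called more than the data, 120 on average, and of these 60.2% moved back. Chosen in one number and measured in the other, where 50% is the value of no change, the shares were 91.4% and 91.1% in S82-2, 80.3% and 77.7% in S14-150, 27.1% and 32.0% in S15-118 and 13.1% and 43.5% in S58-2. In S82-2, 39 of the 52 were called back, and in the other 3 lines 0 were. Over all tested, 270, 191 and 414 probe sets had an unadjusted p under 0.05 (limma) between these lines and aba3-1 without the block. With the block 863, 607 and 1481 did, above the 578 that no change would give. Without the block the difference between replicate numbers enters the spread, so counts below 578 are no sign of fewer changes. With the block, 339 of 576 were called back in S82-2, and 7, 1 and 2 in S14-150, S15-118 and S58-2, while 3, 0, 2 and 3 were called farther from wt. The simulated line was called back in 0 probe sets on average without the block and in 0.06 with it. A line equal to aba3-1 has few calls of any kind, so these values say little about the counts above. With the block the simulations called 1742.5 between aba3-1 and wt on average, against 576 in the data.

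**Figure D4:**
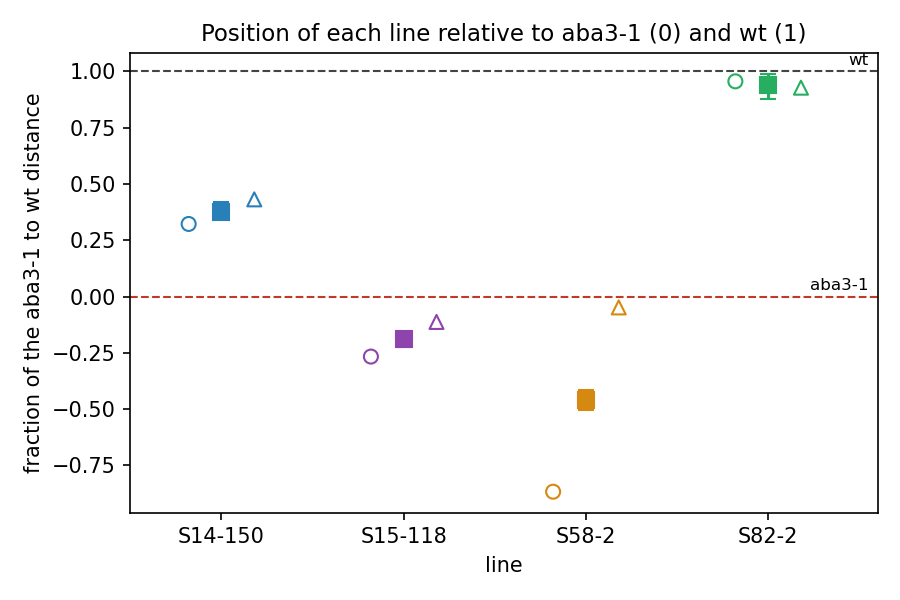
Share of the aba3-1 to wt distance covered by each line (0 is aba3-1, 1 is wt, unitless), with squares for the mean of both choices of probe sets, bars for the bootstrap interval over probe sets, circles for probe sets chosen in replicate number 1 and triangles for those chosen in number 2. S82-2 is at 0.941 and S58-2 at -0.458.

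Genes that set 1 line apart from the other 5 groups were sought next. AT5G61140 was the only call for S14-150 (-3.05, SE 0.18, adjusted p = 0.00120), in both fits. S15-118 had 5, 3 higher and 2 lower (14 and 24 in the blocked fit), led by AT1G33840 (3.51, SE 0.18, adjusted p = 0.000500) and with AT3G43270 lower (-1.14, SE 0.13, adjusted p = 0.0359). S58-2 had 84, 68 higher and 16 lower, but 203 and 213 in the blocked fit. WRKY53 was 2.28 higher (SE 0.26, adjusted p = 0.00933), CHI 3.66 higher (adjusted p = 0.0299) and AT1G16210 -3.65 (adjusted p = 3.2e-05). Against aba3-1 itself, AT1G16210 alone of these was called without the block, and WRKY53 was 1.37 higher (adjusted p = 0.9997). Against wt, CHI was 5.87 higher in S58-2, but also 4.54 higher in S15-118 and 4.13 higher in aba3-1 (the last called in the blocked fit alone). S82-2 had 53, 13 higher and 40 lower (89 and 159 in the blocked fit). RING1, a ubiquitin ligase gene of cell death, was -2.03 (SE 0.19, adjusted p = 0.00625), the phosphatase gene SAL2 -1.94 (adjusted p = 0.00991) and the receptor kinase gene AT4G08850 -1.64 (adjusted p = 0.00846). These are differences from a mean that includes aba3-1 and the other lines. Against wt itself, QQS alone was called in S82-2 without the block, so none of these genes was. Leaving out S58-2 replicate 2 moved the counts to 6 for S58-2 and 41 for S15-118, and leaving out S82-2 replicate 1 gave 0 for S82-2.

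When lines were compared directly, S82-2 and S58-2 had the most calls, 318, 257 higher in S58-2 and 61 lower, but 974 and 903 in the blocked fit. S15-118 and S82-2 differed in 159, 131 higher in S15-118 and 28 lower (681 and 514 in the blocked fit). S14-150 differed from S58-2 in 15, 1 higher and 14 lower (208 and 409 in the blocked fit), from S15-118 in 6, all lower (18 and 58), and from S82-2 in 3, 1 higher and 2 lower (112 and 74). S15-118 differed from S58-2 in 2, both higher (6 and 12). Without S82-2 replicate 1, S58-2 and S82-2 differed in 48, without S15-118 replicate 1, S15-118 and S82-2 in 2, and without S58-2 replicate 1, S14-150 and S58-2 in 63. The F test over all 6 groups called 150 probe sets (1633 in the blocked fit, and 44 without S82-2 replicate 2). The mean of the 4 lines differed from aba3-1 in 0 probe sets with limma and in 4 in the blocked fit. At an unadjusted p under 0.05 (limma) there were 187 without the block and 748 with it, below and above the 578 given earlier.

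AT5G09570 was the single gene called in 2 lines against aba3-1, S14-150 and S15-118, in the same direction. The simulated count for that pair was 0 and the overlap of independent lists 0.000346. The simulated lines were unchanged and so had few calls to share, and independent lists leave out the shared aba3-1 arrays. Neither value is a measure for 2 changed lines on the same controls. The other 5 pairs shared 0 calls. The blocked fit shared 3 calls between S14-150 and S15-118, 6 between S14-150 and S82-2, 3 between S58-2 and S82-2, 2 between S15-118 and S82-2, 1 between S15-118 and S58-2 and 0 between S14-150 and S58-2. The covariance of the changes from aba3-1 exceeded the simulated value by 0.0599 for S14-150 and S82-2 and by 0.025 for S15-118 and S58-2, and lay below it for S58-2 and S82-2 (-0.0520), S15-118 and S82-2 (-0.0351), S14-150 and S58-2 (-0.0275) and S14-150 and S15-118 (-0.00916). Across numbers, where no aba3-1 array is shared, the covariance was 0.0649 for S14-150 and S82-2 and 0.0315 for S15-118 and S58-2, and 0.000194 for S14-150 and S15-118, the pair of the shared call. It was -0.0492 for S58-2 and S82-2, -0.0226 for S15-118 and S82-2 and -0.0227 for S14-150 and S58-2.

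The list of ABA-responsive genes had 1 tested member, XERICO, too few for a list test. XERICO changed by -0.07 in aba3-1 against wt (adjusted p = 0.9996) and was called in none of the 10 comparisons without the block. The cold regulon held 4 tested genes, COR15A, COR15B, COR47 and STZ. None of them was called over all genes tested, nor when adjusted over the list alone, between aba3-1 and wt or S82-2 and aba3-1 without the block. In the blocked fit 2 of the 4 were called lower in aba3-1 than in wt, and all 4 were called between S82-2 and aba3-1, 3 higher and 1 lower. The median of the list was -1.06 in aba3-1 against wt and 1.26 in S82-2 against aba3-1. Camera gave an adjusted p of 0.483 for both (0.741 with an estimated correlation), and 0.0316 in the blocked fit for these and for the mean of the 4 lines against aba3-1. STZ, a zinc finger repressor gene, went the other way, 1.52 in aba3-1 and -1.90 in S82-2. In the photosynthesis list (5 tested, RCA and LHCB4.1 among them) and the list of expansins and xyloglucan endotransglucosylases (3 tested, EXPA8 and EXPA4 among them), 0 members were called over all genes tested and 0 when adjusted over the list alone in the comparisons of aba3-1 with wt and of the lines with aba3-1. Their lowest camera adjusted p was 0.342, for photosynthesis in S58-2, and in all 0 of 30 tests passed, with either correlation. Without S58-2 replicate 2, photosynthesis passed in S58-2 against aba3-1 and wt (adjusted p = 0.0126 in both).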

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

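The tests on S82-2 (wt plants, scaling, 1 poor array), on AT2G21640 and its companions and on the replicate numbers (clock genes, scaling) were chosen only after the results were seen, and the comparisons of the lines were not. Earlier tests of scaling, by median centring (set before the results), by array medians and by the calls in each direction, were dropped, since arrays normalized together have nearly equal medians from the start.

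The 6 direct comparisons between lines showed differences between groups. The test of the difference itself called 318 probe sets between S58-2 and S82-2, 159 between S15-118 and S82-2, 15 between S14-150 and S58-2, 6 between S14-150 and S15-118, 3 between S14-150 and S82-2 and 2 between S15-118 and S58-2.

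S82-2 lay near wt and apart from S58-2 and S15-118 (318 and 159 calls). From S14-150 it differed in only 3 calls without the block (186 with it). Of the pairs of lines, the checks below use S58-2 and S82-2 alone. Quantile normalization makes the arrays alike in distribution, and it moved values by 0.0230 log2 on average. It gave 298 calls between S58-2 and S82-2, 289 of them among the 318. Scaling of a whole array changes its distribution, and the distributions were nearly alike before this step. The 289 calls left afterwards therefore argue against scaling still present in the deposited values. A distortion that leaves the distribution of an array unchanged is not tested by this step. It stays open, as do effects on some probe sets alone. The differences between S58-2 and S82-2 correlated at 0.665 across genes between the replicate numbers, which argues against 1 poor array, and QQS was 4.12 log2 higher than in wt, which argues against plants of the wt group under the S82-2 label. Wild type plants of another seed stock or batch were not tested and stay open. A suppressor mutation that restores most of the wt profile may be a biological explanation, as a hypothesis only.

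Against aba3-1, AT5G09570 was called higher in S14-150 and S15-118 in both fits and AT2G21640 in the blocked fit alone, while AT2G41730 and AT5G51440 were higher but called in neither fit (blocked adjusted p of 0.108 and 0.308 in S14-150, 0.153 and 0.386 in S15-118). Against wt the smallest of their 8 changes was 1.89 (SE 0.61, not called), which argues against low values on the shared aba3-1 arrays. A response to disturbed mitochondria may be a candidate explanation, and the other 5 tested genes of a list of such genes gave a camera p of 0.353 in S14-150 against aba3-1 (median -0.09, members going both ways), but 1.03e-06 in S15-118 (adjusted p = 0.0409 with an estimated correlation), and passed in S14-150 against wt (adjusted p = 0.000708, or 0.0460 with an estimated correlation). Against wt these 5 also passed upward in S15-118 and S58-2 with either correlation (camera adjusted p = 0.0409 and 0.0460 with the estimated one). At the preset correlation, though not with an estimated one, they passed upward in S58-2 against aba3-1 (adjusted p = 0.00186, or 0.0528). The same held upward in aba3-1 against wt (0.00401 or 0.0607) and downward in S82-2 against aba3-1 (0.00534 or 0.0610). The 4 genes changed by at most 0.39 in aba3-1 against wt, so that the explanation stays open. That list was put together and then changed after values were seen, and 1 further locus, AT3G15310, was set aside. Against aba3-1 that locus went the other way, -2.43 in S15-118 and -1.87 in S58-2. It was called there in the blocked fit alone (limma, blocked adjusted p = 0.00120 and 0.0213). The bound that would have excluded the explanation was made to allow for the spread of the members after the p was known. By the earlier bound the explanation would have been excluded.

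The replicate numbers parted all arrays, with 5549 probe sets differing between them. Quantile normalization left 5565, 5342 of them the same probe sets. Of the probe sets called afterwards, 579 were at least 1 log2 higher in number 2 and 506 at least 1 log2 lower. These values argue against scaling still present in the deposited values here too. A distortion that leaves the distribution of an array unchanged stays open. Another harvest time or growth batch could account for the difference between the numbers. Of the 2 tested clock genes, CCL (-3.11) lay past the 90th percentile of all differences and GI (-0.94) at 89.4, so that this stays open. No biological explanation was tested, since no label says what a number stands for.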

How the results depend on the processing

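The fits without the S58-2 arrays, the blocked counts of shared calls and the blocked fits with 1 array left out were chosen after seeing the data; the other settings were not. No called value of a named gene changed sign. Of all 188 values of named genes, 63 changed sign in at least 1 setting, none of them called without the block, nearly all in fits with 1 array left out. The direction with more calls turned in some counts (higher and lower, with those of the fit fixed beforehand in brackets). Without the filter it was 2 and 4 for aba3-1 against wt (43 and 9) and 4 and 6 for S14-150 against wt (4 and 3). With a mean above 6 it was 1 and 0 for S14-150 against S58-2 (1 and 14), and with array weights 13 and 4 for S14-150 against S82-2 (1 and 2). With the block it was 10 and 2 for S58-2 against aba3-1 (0 and 1), 1216 and 1405 for S58-2 against wt (252 and 121), 16 and 38 for S82-2 against wt (1 and 0), and 14 and 24 for S15-118 against the other 5 groups (3 and 2). It was also 203 and 213 for S58-2 against the other 5 groups (68 and 16), 112 and 74 for S14-150 against S82-2 (1 and 2) and 6 and 12 for S15-118 against S58-2 (2 and 0). With the block and without the S58-2 arrays it was 1283 and 1391 for S15-118 against wt (128 and 32), 24 and 61 for S82-2 against wt, 238 and 183 for S14-150 against S82-2 and 916 and 926 for S15-118 against S82-2 (131 and 28). The fold threshold does not apply to the F test and was not run for it. Of the 188, 187 kept their side of the threshold under median centring, 188 under the fold threshold and 176 with the block, where 12 more were called; 53 lost their call with Bonferroni and 29 without the filter. With 1 array left out, 215 of the 896 values so obtained lost their call without the block; with it, 4 did and 26 were newly called. With only the groups compared, 57 of the 170 values in those comparisons lost their call. All counts stayed within 1.5 times under median centring and the fold threshold. Where a count moved, the cause was not tested, except that fewer probe sets were tested with a mean above 6, a stricter adjustment was used with Bonferroni, and fewer arrays estimated the spread with only the groups compared. Since the filter asks for only 2 arrays above 4, signals near background remain among the genes named.

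The replicate numbers pair the arrays, and the block changed most counts. The blocked fit gave 576 for aba3-1 against wt, 10 for S14-150 against aba3-1, 10 for S15-118 against aba3-1, 12 for S58-2 against aba3-1, 677 for S82-2 against aba3-1, 161 for S14-150 against wt and 1657 for S15-118 against wt. The blocked fit also gave 2621 for S58-2 against wt, 54 for S82-2 against wt, 4 for mean of 4 suppressors against aba3-1, 38 for S15-118 against the other 5 groups, 416 for S58-2 against the other 5 groups, 248 for S82-2 against the other 5 groups and 76 for S14-150 against S15-118. The blocked fit also gave 617 for S14-150 against S58-2, 186 for S14-150 against S82-2, 18 for S15-118 against S58-2, 1195 for S15-118 against S82-2, 1877 for S58-2 against S82-2, 1633 for the F test and 3 for calls shared by S14-150 and S15-118. The blocked fit also gave 6 for calls shared by S14-150 and S82-2, 1 for calls shared by S15-118 and S58-2, 2 for calls shared by S15-118 and S82-2, 3 for calls shared by S58-2 and S82-2 and 3 for gene list tests passed. It changed no other call of a gene list and left the call of AT5G61140 for S14-150 as it was. All calls without the block were also called with it.

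Without the filter, the counts came to 6 for aba3-1 against wt, 1 for S14-150 against aba3-1, 2 for S58-2 against aba3-1, 9 for S82-2 against wt, 2 for S14-150 against the other 5 groups, 135 for S58-2 against the other 5 groups and 9 for S14-150 against S58-2. Without the filter, the counts also came to 6 for S14-150 against S82-2, 5 for S15-118 against S58-2 and 0 for calls shared by S14-150 and S15-118. With a mean above 6, the counts came to 14 for aba3-1 against wt, 0 for S14-150 against aba3-1, 1 for S15-118 against aba3-1, 30 for S82-2 against aba3-1, 2 for S14-150 against wt, 32 for S15-118 against wt and 191 for S58-2 against wt. With a mean above 6, the counts also came to 2 for S82-2 against wt, 0 for S14-150 against the other 5 groups, 1 for S15-118 against the other 5 groups, 39 for S58-2 against the other 5 groups, 28 for S82-2 against the other 5 groups, 0 for S14-150 against S15-118 and 1 for S14-150 against S58-2. With a mean above 6, the counts also came to 0 for S14-150 against S82-2, 1 for S15-118 against S58-2, 41 for S15-118 against S82-2, 115 for S58-2 against S82-2, 43 for the F test and 0 for calls shared by S14-150 and S15-118. With quantile normalization, the counts came to 36 for S14-150 against S58-2 and 2 for calls shared by S14-150 and S15-118. With trend and robust variance, the counts came to 1 for S14-150 against aba3-1, 8 for S14-150 against S58-2, 1 for S14-150 against S82-2 and 0 for calls shared by S14-150 and S15-118. With array weights, the counts came to 134 for S82-2 against aba3-1, 147 for S58-2 against wt, 10 for S15-118 against the other 5 groups, 12 for S58-2 against the other 5 groups, 100 for S82-2 against the other 5 groups, 5 for S14-150 against S58-2 and 17 for S14-150 against S82-2. With array weights, the counts also came to 248 for S15-118 against S82-2 and 175 for S58-2 against S82-2. With Bonferroni adjustment, the counts came to 1 for aba3-1 against wt, 1 for S14-150 against aba3-1, 1 for S15-118 against aba3-1, 1 for S82-2 against aba3-1, 3 for S14-150 against wt, 8 for S15-118 against wt and 20 for S58-2 against wt. With Bonferroni adjustment, the counts also came to 3 for S15-118 against the other 5 groups, 6 for S58-2 against the other 5 groups, 5 for S82-2 against the other 5 groups, 2 for S14-150 against S15-118, 5 for S14-150 against S58-2, 1 for S14-150 against S82-2 and 10 for S15-118 against S82-2. With Bonferroni adjustment, the counts also came to 19 for S58-2 against S82-2, 13 for the F test and 0 for calls shared by S14-150 and S15-118. With only the groups compared, limma called 0 probe sets in each of the 15 comparisons of 2 groups, where 2 degrees of freedom estimate the spread. From 79 (S15-118 against S58-2) to 1027 (S58-2 against wt) had an unadjusted p under 0.05. The 578 of no change is no reference here, since the arrays are paired by number and these fits have no block. Without the S58-2 arrays, the counts came to 1 for S14-150 against aba3-1, 13 for S14-150 against wt, 0 for S82-2 against wt and 0 for calls shared by S14-150 and S15-118. With the block and without the S58-2 arrays, the counts came to 954 for aba3-1 against wt, 64 for S14-150 against aba3-1, 30 for S15-118 against aba3-1, 1001 for S82-2 against aba3-1, 490 for S14-150 against wt, 2674 for S15-118 against wt and 85 for S82-2 against wt. With the block and without the S58-2 arrays, the counts also came to 258 for S14-150 against S15-118, 421 for S14-150 against S82-2, 1842 for S15-118 against S82-2, 5 for calls shared by S14-150 and S15-118, 48 for calls shared by S14-150 and S82-2 and 3 for calls shared by S15-118 and S82-2. With a choice at 0.5 log2, the values were 0.299 for recovery of S14-150 and 0.898 for recovery of S82-2. On the called probe sets, the values were -0.0721 for recovery of S15-118 and 1.034 for recovery of S82-2, and, within 1 SD of the 2 choices, -0.271 for recovery of S58-2 and 0.431 for recovery of S14-150. With a choice at 1.5 log2, the values were 0.964 for recovery of S82-2. As a covariance ratio, the values were 0.914 for recovery of S82-2.

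Each array was left out in turn, without and with the block; the lone array of its group is assumed to vary like the other groups, and without the block the difference between replicate numbers then enters the comparison. The ranges run over both fits, except those of shared calls and gene list tests, which are from the fits without the block alone. Leaving out 1 array gave 1 to 328 for aba3-1 against wt, 0 to 162 for S14-150 against wt, 8 to 1147 for S15-118 against wt, 71 to 3380 for S58-2 against wt, 0 to 6 for S82-2 against wt, 0 to 12 for S14-150 against the other 5 groups and 1 to 237 for S15-118 against the other 5 groups. Leaving out 1 array also gave 6 to 1445 for S58-2 against the other 5 groups, 0 to 376 for S82-2 against the other 5 groups, 44 to 2513 for the F test, 0 to 9 for S14-150 against aba3-1, 0 to 12 for S15-118 against aba3-1, 1 to 548 for S58-2 against aba3-1 and 0 to 420 for S82-2 against aba3-1. Leaving out 1 array also gave 0 to 36 for mean of 4 suppressors against aba3-1, 0 to 1 for calls shared by S14-150 and S15-118, 0 to 1 for calls shared by S15-118 and S58-2, 0 to 9 for S14-150 against S15-118, 1 to 1433 for S14-150 against S58-2, 0 to 29 for S14-150 against S82-2 and 1 to 80 for S15-118 against S58-2. Leaving out 1 array also gave 2 to 730 for S15-118 against S82-2, 48 to 2648 for S58-2 against S82-2 and 0 to 2 for gene list tests passed. The counts of shared calls for the other pairs of lines stayed at 0 in the fits without the block.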

Other observations

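The tests of genes neighbouring AT1G16210 and AT5G61140 were set up before their values were seen. The tests of chloroplast genes and gene families and the differences between replicate numbers were chosen only after the data were seen. So were the no-change values and the overlap of S82-2 with aba3-1.

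The median signal of transcripts encoded in the chloroplast genome was lower on both S14-150 arrays and on 1 of the S58-2 arrays, but 0 of 65 were called against aba3-1 in either fit by limma. The median over 65 such genes was 9.43 and 9.59 on the S14-150 arrays, and 10.06 and 9.45 on those of S58-2, against 10.29 and 10.45 in aba3-1 and 10.08 and 10.73 in wt. Against aba3-1, 59 of the 65 were lower, and the median change was -0.36 (-0.31 in replicate number 1 and -0.40 in number 2). The ATP synthase gene atpF was at 8.78 ± 0.77 (SD, n = 2) in S14-150 and 10.41 ± 0.03 in aba3-1. Against wt, 2 of the 65 were called lower in S14-150, in the blocked fit alone, atpF (-1.56, adjusted p = 0.653, blocked adjusted p = 0.0341) and ndhH (-1.76, adjusted p = 0.453, blocked adjusted p = 0.0477), and 9 were called lower in S58-2 in that fit. In S58-2 the median change from aba3-1 was -0.31, from -0.01 in number 1 and -0.74 in number 2. The set was called by camera with the preset correlation in both lines, and had an adjusted p of 0.593 with an estimated correlation. None of the 27 sets tested, 26 gene families among them, passed with an estimated correlation.

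Genes that differed between the replicate numbers in all 6 groups included HYH, a light-signalling transcription factor gene, 4.63 log2 higher in number 2, and the flavonoid glucosyltransferase gene UGT78D2, 3.80 higher. COR15A was lower in number 2 (-1.91), as was the anthocyanin gene DFR (-2.08). Of the 54 probe sets called between S82-2 and wt in the blocked fit, 26 of the 29 shared with aba3-1 were not called between S82-2 and aba3-1 (the same wt arrays serve both comparisons with wt), among them ZW9 (-1.99 in S82-2 and -2.30 in aba3-1).

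AT1G16210 was low in S58-2 alone and AT5G61140 in S14-150 alone, so each may mark a mutated gene of its line. A deleted stretch of the chromosome would lower neighbours too. Of the 10 nearest tested neighbours of AT1G16210, 0 were lower by 1 log2 or more (range -0.21 to 0.42), and of those of AT5G61140 also 0 (-0.36 to 0.21). Both counts are of measured changes, not of limma calls. This argues against a deletion that reaches the tested neighbours, the farthest of which lie 29 and 27 genes away. A change within the gene or a smaller deletion was not tested. AT1G16210 lies 41 genes from ABA3. AT3G43270 was also lower in S15-118 alone, by a smaller change (-1.14 against the other 5 groups). Of its 10 nearest tested neighbours, 0 were lower than in aba3-1 by 1 log2 or more (-0.48 to 0.42), the farthest 113 genes away.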
